A study of Mus musculus with 12 samples.

How the data were processed

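Single-cell RNA was measured with Seq-Well, in which cells settle into picolitre wells with barcoded mRNA capture beads, and libraries were made with Illumina Nextera XT, per the labels' protocols. There were 12 mouse libraries, 4 per group. The stimulated and ex vivo groups each came from the same mice 1 to 4, and their CD8 T cells were sorted with an MHC tetramer loaded with a peptide of the human papillomavirus E7 protein, per the labels. The stimulated libraries are of cells given antigen. The 4 libraries of the third group hold unstimulated T cells of wild-type BL6 mice that were enriched with magnetic beads without the tetramer sort. Into these, OT-I cells with intact Rag had been mixed at 10%, 1%, 0.1% or 0.01%, with 1 library per percentage. OT-I cells carry a transgenic receptor for an ovalbumin peptide. Nothing in the labels says that these 4 libraries came from separate animals, so p-values that involve them measure only the spread between these libraries, which may be technical.

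The deposited files give whole-number UMI counts per gene and barcode, with 2000 barcodes per file and 28139 genes over all files, per the file headers and the values. Reads were demultiplexed with bcl2fastq and aligned with STAR to the mm10 build, per the submitters' processing notes. The versions, the gene annotation used for counting and the rule by which 2000 barcodes were kept are not given in the sources used here. The lowest UMI total of a listed barcode ran from 2 to 2999, so the libraries were not limited by one UMI minimum. The files of mouse 4 are named in another pattern than those of mice 1 to 3, so they may come from another processing run, and each comparison was also made without that mouse. No 2 libraries shared more than 3 barcodes.

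Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. The kept cells numbered 1514, 1970, 1967 and 1724 in stimulated mice 1 to 4, 1908, 1954, 1972 and 1703 in ex vivo mice 1 to 4, and 1947, 1982, 1953 and 1889 in the bead-enriched libraries from 10% down to 0.01%. No cell count stated by the study was used here. Scrublet called 0.0512% to 0.881% of the cells of a library doublets, which is too few for a caller that has worked, so no cells were removed as doublets, and doublets were weighed by marker genes instead. Of the UMIs, 7.15% to 44.4% per library fell on 7 features that hold rRNA-like reads (Gm26924, mt-Rnr1, mt-Rnr2, mmu-mir-6236, Lars2, Gm23935 and Gm15564). Intervals and floors cover counting error only, at 95%, and a count of 0 was given a floor of 3 counts.

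Counts were summed per library and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 5%. Log2 fold changes come from that fit. CPM are a library's summed counts per 1e6 of its total over the tested genes, after scaling by its TMM factor. The CPM of a gene in the ex vivo libraries therefore differ between the comparisons, which also use different cells. The first comparison was stimulated against ex vivo over all kept cells. The other was ex vivo against bead-enriched over CD8-detected cells, defined by at least 1 UMI of Cd8a or Cd8b1 and none of 6 markers of other cells, among them Cd4, Cd79a, Cd79b, Ms4a1 and Lyz2. These 8 selecting genes are not named as findings of that comparison. There were 1742, 1759, 1841 and 1552 such cells in ex vivo mice 1 to 4 and 1459, 1568, 1526 and 1183 in the bead-enriched libraries. The test was checked on simulated counts drawn from the real means and library sizes with 200 changed genes. In the first comparison it found 79% of the 2-fold and 97% of the 4-fold changes, with 8 false calls (4.35%), over 10459 genes. In the other it found 82% and 97%, with 12 false calls (6.28%), over 10778 genes. The simulated changes were balanced up and down and had no effect of mouse. In the real data 5636 and 7818 genes were called, so the check does not cover normalization or false calls at that scale.

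The tests, the alternatives, 28 gene lists (15 of biology, 3 of sample quality and 10 of other cell types) and the rule for naming genes were fixed before the data were examined. From each biology list the rule takes the 2 members with the largest absolute log2 fold change among those past 5% and changed the same way in every mouse, or, against the bead-enriched libraries, with groups that do not overlap. Where fewer passed, the members with the smallest p were taken. It adds the 5 highest and 5 lowest fold changes with a mean of at least 20 CPM, always Ifng, Tnf, Il2, Xcl1, Ccl3, Ccl4 and Gzmb, and from each other list the member with the highest mean count. Other list members named as examples were chosen after their values were seen. Lists were tested with camera (limma 3.58.1, preset correlation), with the estimated correlation and fry as alternatives. Of the lists, 26 had at least 2 tested members, and the erythroid and platelet lists had 1 each and were not tested as lists. Listed symbols were matched to the older symbols that the files use.

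For shares of cells with a UMI, each cell was thinned to 500 UMIs, and group means were compared with an exact two-sided permutation test, whose smallest p with 4 against 4 is 0.0286. B-like cells within the sort served as the background for these shares. Co-detection of gene pairs was measured as a log2 odds ratio per mouse, with 0.5 added to each cell of the 2 by 2 table. The numbers of co-detected cells were also set against those expected from the hypergeometric distribution in each mouse, which needs no added constant. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (resolution 0.6) on 2000 variable genes and 30 principal components with 15 neighbours, without the rRNA-like and mitochondrial genes. Clusters were named only from marker genes fixed beforehand. The OT-I series has no replicates, so shares carry exact Clopper-Pearson intervals and summed counts exact Poisson intervals. Its genes were named by size, with at least 100 UMIs over the 4 libraries, a monotone order and at least 2-fold between 10% and 0.01%. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

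The stimulated and ex vivo libraries pair by mouse, since the labels number the same mice in both. Over the 5000 genes compared, the deviations of same-mouse libraries from their group means correlated at 0.235, 0.622, 0.227 and 0.787 in mice 1 to 4, and those of different mice at -0.56 to 0.333. A fit with mouse as a block was an alternative. The other alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, other cell filters, libraries thinned to the smallest total, a mean of scaled cells with limma, subsets of clusters, the rRNA-like features left out, thinning to 1000 UMIs, a resolution of 1.0, and each replicate or library left out in turn. Gene positions are from GENCODE vM21 on GRCm38, the assembly that UCSC calls mm10, where 92 of 96 named symbols were found. Nucleotide sequences of receptors were not analysed here. Results of a few single genes that were tested and counted are not reported here.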

Results

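Transcripts of single T cells were counted in 12 mouse libraries. Tetramer-sorted CD8 T cells specific for a papillomavirus E7 peptide were profiled from 4 mice, both after antigen stimulation and directly ex vivo. Bead-enriched T cells, with OT-I cells mixed in at 4 percentages, filled the other 4 libraries. The kept cells held 10051526, 12909944, 11684355 and 8665135 UMIs in stimulated mice 1 to 4 and 8432460, 5116646, 9572291 and 2973829 in ex vivo mice 1 to 4. The bead-enriched libraries held 8865483, 7921831, 5914447 and 8805117 UMIs from 10% down to 0.01% OT-I. The median cell had 4357 to 5848 UMIs in the stimulated libraries, 1562 to 4385 in the ex vivo ones and 2556 to 4124 in the bead-enriched ones. The rRNA-like features took 27.2 ± 6.33% of UMIs in the stimulated, 34.6 ± 7.81% in the ex vivo and 11.3 ± 6.88% in the bead-enriched libraries. All errors are SDs over the n = 4 libraries of a group.

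The comparison of stimulated with ex vivo cells asked how transcription differs in these sorted cells after antigen stimulation. No library held sorted cells handled in the same way without antigen, so antigen and handling cannot be separated here. Among genes with a mean of at least 20 CPM, the 5 highest folds were those of Ccl1, Ccl3, Xcl1, Ccl4 and Il2. Ccl3, which attracts monocytes and T cells, was at 1476 ± 403 CPM in stimulated and 16.6 ± 6.48 CPM in ex vivo cells, and its neighbour Ccl4 was at 2127 ± 158 against 30.7 ± 7.84 CPM. Xcl1, the attractant of cross-presenting dendritic cells, was at 160.3 ± 65.0 against 2.02 ± 0.475 CPM, and Il2, the T cell growth factor, at 59.9 ± 14.7 against 0.993 ± 0.611 CPM. Ifng, the macrophage-activating interferon, was at 1877 ± 824 against 67.2 ± 24.7 CPM. Ccl1, a ligand of Ccr8, had 855, 2381, 429 and 640 UMIs in stimulated mice 1 to 4 and 0 in all 4 ex vivo libraries, which puts it at least 865-fold higher against a floor of 3 counts over the group.

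Of the 10459 genes tested with edgeR, 5636 changed at 5%, 2892 higher and 2744 lower in stimulated cells, and 5533 of them had the same direction in all 4 mice. Changes above 2-fold were fewer, with 1161 higher and 906 lower. With limma on means of scaled cells, 4152 genes changed, 2610 higher and 1542 lower. Without mouse 4, whose files are named in another pattern, 5765 genes changed, and mouse 4 alone gives no test.

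Of 13 effector cytokines and chemokines tested, 11 rose and none fell, with a median log2 fold change of 6.04, which was also 6.04 with Ccl1 and Il3 at their lower bounds (camera adjusted p = 5.04e-16; adjusted p = 0.0355 with an estimated correlation). By edgeR, the log2 fold changes were 6.54 for Ccl3 (adjusted p = 1.21e-08), 6.14 for Ccl4 (adjusted p = 1.47e-09), 6.30 for Xcl1 (adjusted p = 1.33e-07), 6.04 for Il2 (adjusted p = 1.75e-08) and 4.81 for Ifng (adjusted p = 3.64e-07). Each was higher in 4 of 4 mice. Tnf, an inflammatory cytokine, rose by less, at 43.9 ± 17.5 against 10.4 ± 5.98 CPM (log2 fold change 2.06, edgeR adjusted p = 0.00035). Il3, a growth factor for myeloid cells, was at 8.16 ± 6.23 CPM and had 0 UMIs in every ex vivo library, which is at least 74.1-fold. The fitted log2 fold changes were 12.63 for Ccl1 (11.95 without the stimulated library of mouse 2) and 9.16 for Il3 (8.55 without mouse 1). Il10, an inhibitory cytokine, rose by a log2 fold change of 4.25. With limma on means of scaled cells, Il2 was at 4.57 and Xcl1 at 5.39. The members that did not pass were Csf1 at 0.35 and Lta at 0.43. Adjusted over the list alone, 11 rose and none fell. In this and the later lists, the counts adjusted over the list alone are the same as over all genes except where both are given.

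**Figure D1:**
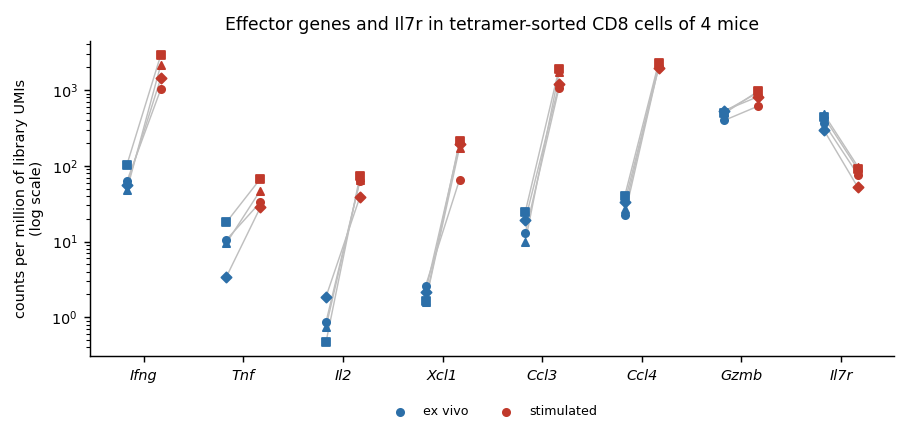
Normalized counts (CPM), on a log axis, of 8 genes in stimulated (red) and ex vivo (blue) libraries, with a point per library whose shape stands for the mouse and grey lines that join the libraries of a mouse. Ccl3 lies at 1476 against 16.6 CPM on average and Il7r at 79.1 against 395, and the groups do not overlap for either gene.

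Transcription factors induced through the T cell receptor rose together, with 16 of 25 higher, 1 lower and a median of 1.41 (camera adjusted p = 5.65e-14; adjusted p = 0.0035 with an estimated correlation). Egr2, an early response factor that restrains T cells, was at 24.9 ± 6.45 against 0.884 ± 0.271 CPM, and Irf8, an interferon regulatory factor also used by effector CD8 cells, at 428 ± 26.1 against 20.02 ± 5.99 CPM. Irf4, Myc and Nr4a1, which respond to receptor signal, had log2 fold changes of 3.70, 3.66 and 2.97. Tbx21, the effector factor T-bet, fell by 0.51 on the log2 scale. Of 18 activation and costimulatory surface molecules, 15 rose and none fell (16 adjusted over the list alone), with a median of 1.699 (camera adjusted p = 2e-09; adjusted p = 0.00424 with an estimated correlation). Tnfsf11, known as RANKL, was at 29.4 ± 2.80 against 1.86 ± 0.762 CPM, and Tnfsf14, known as LIGHT, at 95.3 ± 16.01 against 7.68 ± 1.68 CPM. Il2ra, the high-affinity chain of the Il2 receptor, and Tnfrsf9, the costimulatory receptor 4-1BB, rose by log2 fold changes of 2.60 and 2.28.

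Ribosome biogenesis genes and MYC targets rose nearly as a whole, with 29 of 30 higher, none lower (30 adjusted over the list alone) and a median of 2.39 (camera adjusted p = 2.14e-52; adjusted p = 0.0035 with an estimated correlation). Srm, the spermidine synthase, was at 105 ± 12.03 against 2.61 ± 0.836 CPM (log2 fold change 5.21), and Polr1b, a subunit of the RNA polymerase that transcribes rRNA, at 57.9 ± 14.7 against 3.197 ± 0.390 CPM. Genes of cytokine signalling feedback rose in 16 of 24 cases and fell in 1, with a median of 0.67 (camera adjusted p = 0.00166; adjusted p = 0.0402 with an estimated correlation). Among them, Spry1, an inhibitor of Ras signalling, was at 46.6 ± 15.1 against 2.33 ± 0.603 CPM and Dusp4, a MAP kinase phosphatase, at 107 ± 39.7 against 7.17 ± 1.68 CPM. Of the oxidative phosphorylation genes, 18 of 30 rose and none fell, with a median of 0.54 (camera adjusted p = 0.00166), a call lost with the estimated correlation (adjusted p = 0.613 with an estimated correlation). Atp5g1, a subunit of the ATP synthase, was at 27.1 ± 1.82 against 4.72 ± 2.15 CPM, and Cycs, which is cytochrome c, at 8.39 ± 2.06 against 2.80 ± 0.671 CPM. The mitochondrially encoded genes, by contrast, had 0 of 9 called in either direction by edgeR and a median of -0.08 (camera adjusted p = 0.678).

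Glycolysis and lipid synthesis were not called as lists by camera, while lipid synthesis passed with fry (adjusted p = 0.00203). Of 22 glycolysis and hypoxia genes, 8 rose and 3 fell (median 0.27, camera adjusted p = 0.561), and of 18 cholesterol and lipid genes 7 rose and 2 fell (median 0.19, camera adjusted p = 0.312). Single members moved strongly: Slc16a1, a lactate carrier, was at 188 ± 47.2 against 40.1 ± 2.06 CPM, Acaca, the acetyl-CoA carboxylase, at 28.5 ± 3.83 against 6.60 ± 0.881 CPM, and Fasn, the fatty acid synthase, at 103 ± 11.7 against 29.2 ± 3.73 CPM. Pgam1, a glycolytic mutase, rose by a log2 fold change of 1.07 (edgeR adjusted p = 0.0162). That call ended without mouse 1 (0.69, adjusted p = 0.138), without the ex vivo library of mouse 1 (0.86, adjusted p = 0.0585) and with limma on means of scaled cells (0.95, adjusted p = 0.0564).

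Inhibitory receptors rose in 5 of 10 cases and fell in none, with a median of 0.52 (camera adjusted p = 0.00389), a call lost with the estimated correlation (adjusted p = 0.136 with an estimated correlation). Cd160, a receptor for the herpesvirus entry mediator, was at 42.3 ± 5.22 against 1.45 ± 1.10 CPM, and Havcr2, known as TIM-3, at 197 ± 38.9 against 34.5 ± 13.1 CPM. Pdcd1, known as PD-1, had a log2 fold change of 0.06 and was not called. The cytotoxic list held movement both ways, with 7 of 15 higher and 3 lower (median 0.52, camera adjusted p = 0.501, fry adjusted p = 0.0249). Gzmb, the granzyme B protease, rose from 487 ± 61.7 to 835 ± 159.6 CPM (log2 fold change 0.78, edgeR adjusted p = 0.000908), and Serpinb9, its inhibitor, from 321 ± 30.8 to 829 ± 127 CPM. Gzmk, another granzyme, fell from 109.9 ± 63.1 to 14.98 ± 11.7 CPM (log2 fold change -2.86, edgeR adjusted p = 0.000673; -3.48 without the stimulated library of mouse 4).

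Receptors of resting and recirculating T cells were lower after stimulation. Il7r, the receptor for the survival cytokine IL-7, was at 79.1 ± 20.1 against 395 ± 81.9 CPM (log2 fold change -2.32, edgeR adjusted p = 1.47e-06), and S1pr1, which guides exit from lymphoid tissue, at 106 ± 13.4 against 406 ± 62.5 CPM. Of 20 naive and memory quiescence genes, 11 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.00405; adjusted p = 0.591 with an estimated correlation, so this call was lost). Effector differentiation genes and NK-type receptors fell in 17 of 27 cases and rose in 2, with a median of -0.83 (camera adjusted p = 0.00104; adjusted p = 0.365 with an estimated correlation, so this call was lost too). Cxcr3, a chemokine receptor of effector cells, was at 26.4 ± 6.65 against 161 ± 16.1 CPM, and Klrb1c, known as NK1.1, at 1.14 ± 0.835 against 7.35 ± 2.08 CPM (log2 fold change -2.68; -3.29 without the stimulated library of mouse 4). Zeb2, a repressor of memory fate, and Cx3cr1, a receptor of terminal effector cells, rose by 2.47 and 2.29 on the log2 scale. The 5 lowest folds among genes with a mean of at least 20 CPM also took in Dtx4, a Deltex ubiquitin ligase, at 5.92 ± 1.16 against 55.2 ± 14.1 CPM, Sorl1, a sorting receptor, at 108 ± 8.57 against 552 ± 63.2 CPM, and Gm14446, a predicted gene, at 11.8 ± 3.08 against 58.8 ± 16.97 CPM. Gm14446 was also a top gene of a cluster of sorted cells led by interferon-induced genes such as Ifit3, Ifit1 and Mx1.

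Interferon-induced and cell cycle genes were lower too. Of 29 genes of the type I interferon response, 17 fell and none rose, with a median of -0.90 (camera adjusted p = 0.00626), a call lost with the estimated correlation (adjusted p = 0.667 with an estimated correlation) and with fry (adjusted p = 0.0678). With mouse as a block this call was kept (camera adjusted p = 8.32e-08), with 24 genes lower and none higher. Mean log2 CPM over the list fell in each mouse, from 5.72, 5.80, 5.36 and 4.10 ex vivo to 4.76, 4.61, 4.49 and 3.21 in stimulated mice 1 to 4. Mouse 4 was lowest in both groups. Oas3, an antiviral synthetase, was at 6.87 ± 4.57 against 27.8 ± 14.9 CPM, and I830012O16Rik, the older symbol of Ifit3b, at 2.68 ± 1.93 against 12.2 ± 7.28 CPM. Of 36 cell cycle genes, 19 fell and 3 rose, with a median of -0.59 (camera adjusted p = 0.0172; adjusted p = 0.613 with an estimated correlation, so this call was lost). Mki67, a proliferation marker, fell by 1.42 and Tk1, a thymidine kinase of S phase, by 1.52 on the log2 scale, while Pcna, the replication clamp, rose by 0.92. Ccnb2, a mitotic cyclin, was at 0.833 ± 0.623 against 2.72 ± 1.29 CPM (edgeR adjusted p = 0.0119), and its call ended without mouse 1 (-1.62, adjusted p = 0.0574) and without the ex vivo library of mouse 3 (-1.39, adjusted p = 0.0685). In the T cell receptor complex, 7 of 17 genes fell and 3 rose (median -0.27, camera adjusted p = 0.102, fry adjusted p = 0.0214). Lck, the proximal receptor kinase, was at 218 ± 25.6 against 517 ± 75.5 CPM and Cd8b1, the CD8 beta chain, at 526 ± 83.7 against 886 ± 144 CPM, while Zap70, the kinase downstream of Lck, rose by 0.56.

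**Figure D2:**
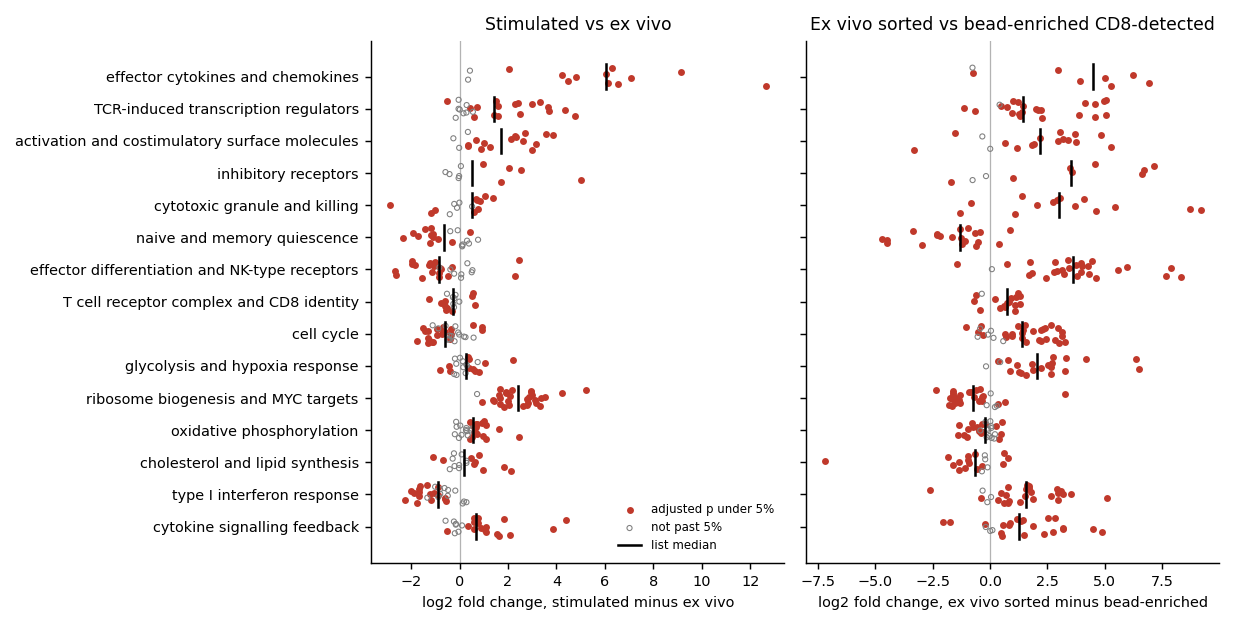
Log2 fold changes of the members of the 15 biology lists, stimulated against ex vivo on the left and ex vivo against bead-enriched on the right, with a point per gene (filled past 5%, open otherwise) and a line at the list median. Effector cytokines have a median of 6.04 on the left, and effector differentiation genes one of -0.83 on the left and 3.60 on the right.

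Lists of sample quality moved alongside these groups. Of 14 heat shock and tissue handling genes, 7 rose and none fell, with a median of 0.83 (camera adjusted p = 0.0289; adjusted p = 0.591 with an estimated correlation and 0.0528 without mouse 3). Hspa5, a chaperone of the endoplasmic reticulum, was at 1935 ± 205 against 713 ± 128 CPM. Of 49 cytosolic ribosomal proteins, 31 rose and none fell (32 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.00182; adjusted p = 0.637 with an estimated correlation). Rps3, its most abundant member, did not pass, at 2869 ± 271 against 2668 ± 179.9 CPM. The rRNA-bearing mt-Rnr2 was at -0.43 (edgeR adjusted p = 0.105) and passed with mouse as a block (-0.44, adjusted p = 0.00896), without mouse 4 (-0.40, adjusted p = 0.0361) and with DESeq2 (-0.42, adjusted p = 0.0270).

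Markers of other cell types gave no list called by camera. With fry, the plasma cell list passed (adjusted p = 0.0149). So did the monocyte, macrophage and neutrophil list (fry adjusted p = 0.0116) and the gamma delta T cell list (fry adjusted p = 0.0224). Plasma cell genes had 2 of 4 higher (median 0.45, camera adjusted p = 0.387), with Xbp1, a factor of secretory cells that activated T cells also use, at 147 ± 11.5 against 86.2 ± 8.45 CPM. The B cell list had 1 of 8 lower (median 0.03 and mean -0.02, camera adjusted p = 0.830), the class II list 1 of 5 lower (median -0.44, adjusted p = 0.627) and the monocyte, macrophage and neutrophil list 2 of 4 lower (median -0.50, adjusted p = 0.421). The dendritic cell list had 1 of 5 lower, and 0 adjusted over the list alone, with a median of 0.13, a mean of -0.17 and a downward test (camera adjusted p = 0.849). The NK cell list had 1 of 4 lower (median -0.00, camera adjusted p = 0.677), and the gamma delta T cell list 2 of 3 lower (median -0.94, adjusted p = 0.501). The CD4 and regulatory T cell list had 3 of 8 higher and 1 lower, with a median of -0.13, a mean of 0.33 and an upward test (camera adjusted p = 0.733).

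The most abundant members of these lists mostly did not pass. Cd74, the class II invariant chain, was at 32.2 ± 15.3 against 30.7 ± 22.8 CPM (edgeR adjusted p = 0.969), Bst2 at 0.13, Car2 at -0.64 and Itga2b at -0.08 on the log2 scale. Cd163l1, a scavenger receptor of gamma delta cells, fell from 4.17 ± 2.01 to 1.34 ± 0.825 CPM (log2 fold change -1.64, edgeR adjusted p = 0.00997), a call lost without the ex vivo library of mouse 3 (-1.23, adjusted p = 0.0655). Ctla4, an inhibitory receptor, was at -0.41 (adjusted p = 0.261), Eomes, a factor of NK and memory CD8 cells, at 0.94 (adjusted p = 0.0744), and Ighm, the IgM heavy chain, at -0.45 (adjusted p = 0.0837). With mouse as a block these 3 passed, at -0.47 (adjusted p = 0.000389), 1.08 (adjusted p = 6.99e-06) and -0.46 (adjusted p = 0.0275). Leaving out 1 library or mouse also let calls through: Ctla4 without stimulated mouse 2 (-0.73, adjusted p = 0.0389), Eomes without mouse 4 (1.21, adjusted p = 0.0024) or its ex vivo library (1.51, adjusted p = 0.00233), and Ighm without mouse 2 (-0.63, adjusted p = 0.0407) or its ex vivo library (-0.57, adjusted p = 0.0331). Cst3, a protease inhibitor of myeloid cells, was at 0.18 (adjusted p = 0.217) and passed without the ex vivo library of mouse 1 (0.29, adjusted p = 0.0414).

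On GRCm38, Ifng lies on chromosome 10 at 118441046 to 118445892, Il2 on chromosome 3 at 37120523 to 37125959 and Xcl1 on chromosome 1 at 164931644 to 164935527. Ccl3, at 83647844 to 83649355, and Ccl4, at 83662584 to 83664683, are neighbours on chromosome 11. Il7r lies on chromosome 15 at 9505788 to 9530176, and Gzmk on chromosome 13 at 113171608 to 113225908. All of these are annotated as protein-coding genes.

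Within single cells, the same genes were asked for by the share of cells with a UMI. At 500 UMIs per cell, Ccl4 was seen in 30.2 ± 2.32% of stimulated and 1.39 ± 0.494% of ex vivo cells, Ccl3 in 21.2 ± 4.44% and 0.671 ± 0.289%, and Ifng in 16.3 ± 5.05% and 2.89 ± 0.552%. Without thinning, Ifng was seen in 51.8 ± 15.98% and 13.6 ± 3.94% of cells. Tnfrsf9 was seen in 42.8 ± 7.63% of stimulated and 11.8 ± 3.17% of ex vivo cells. Xcl1 (2.76 ± 0.724% against 0.109 ± 0.0673%), Tnf (1.51 ± 0.497% against 0.475 ± 0.347%), Il2 (1.16 ± 0.227% against 0.0674 ± 0.0791%) and Egr2 (1.06 ± 0.675% against 0.0409 ± 0.0508%) were seen in few cells. Il7r was seen in 3.57 ± 0.951% against 14.6 ± 2.59% of cells, and Mki67 in 1.27 ± 0.347% against 3.02 ± 0.880%. Thinning left out no cells at this depth.

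For 11 of the 14 genes, each named above or Nr4a1, the exact permutation p was 0.0286, the smallest that 4 against 4 can give (adjusted p = 0.0364). That test leaves out the pairing by mouse. In a paired sign-flip test, whose p cannot go below 0.125 with 4 mice, none of these genes could pass. The unthinned shares for these genes were 60.8 ± 6.84% against 6.09 ± 1.87% for Ccl4, 51.8 ± 11.3% against 3.23 ± 0.753% for Ccl3, 78.6 ± 7.67% against 35.8 ± 12.7% for Tnfrsf9, 8.94 ± 2.39% against 0.434 ± 0.146% for Xcl1, 10.8 ± 3.78% against 2.62 ± 1.32% for Tnf, and 3.87 ± 0.720% against 0.267 ± 0.114% for Il2. They were 8.18 ± 1.72% against 0.210 ± 0.0905% for Egr2, 54.8 ± 3.24% against 10.6 ± 3.88% for Nr4a1, 18.7 ± 4.35% against 42.8 ± 12.7% for Il7r and 4.97 ± 0.910% against 9.19 ± 2.63% for Mki67. Gzmb, at 24.04 ± 3.72% against 18.3 ± 2.97% (64.0 ± 6.75% against 50.2 ± 7.18% unthinned), and Cd69, an early activation marker, at 5.10 ± 0.792% against 3.71 ± 0.771% (26.4 ± 4.39% against 17.03 ± 5.72% unthinned), did not pass (exact permutation p = 0.0571, adjusted p = 0.0615 for each).

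B-like cells within the sort gave the background. There were 42 in the stimulated libraries, with a median of 4407 UMIs against 5293 over all cells, and 40 in the ex vivo ones, with 3732.5 against 3144. At 500 UMIs, Ifng was seen in 1 and Ccl3 in 1 of the 42, which allows up to 12.6% for each, Ccl4 in 2 (up to 16.2%), Tnfrsf9 in 4 (up to 22.6%) and Gzmb in 0 (up to 8.41%), by Clopper-Pearson limits. The stimulated shares of Ccl3, Ccl4, Gzmb and Tnfrsf9 lay above those limits in every library, and that of Ifng in all but mouse 1 (10.7%). Nr4a1, at 17.3 ± 2.08% of stimulated and 2.73 ± 0.921% of ex vivo cells, was seen in 11 of the 42 (26.2%) and 13 of the 40 (32.5%). That ex vivo share is far above the one over all cells, so B-like cells give no background for Nr4a1. Shares of Tnf, Il2, Xcl1, Egr2, Cd69 and Mki67 lay within what so few B-like cells allow. In the ex vivo libraries, only Gzmb and Tnfrsf9, each with 0 of 40 (up to 8.81%), had a mean share above it, and Tnfrsf9 in mouse 4 (7.46%) did not reach it. Il7r was seen in 6 of the 40 (15%), so the ex vivo Il7r share was not above this background.

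**Figure D3:**
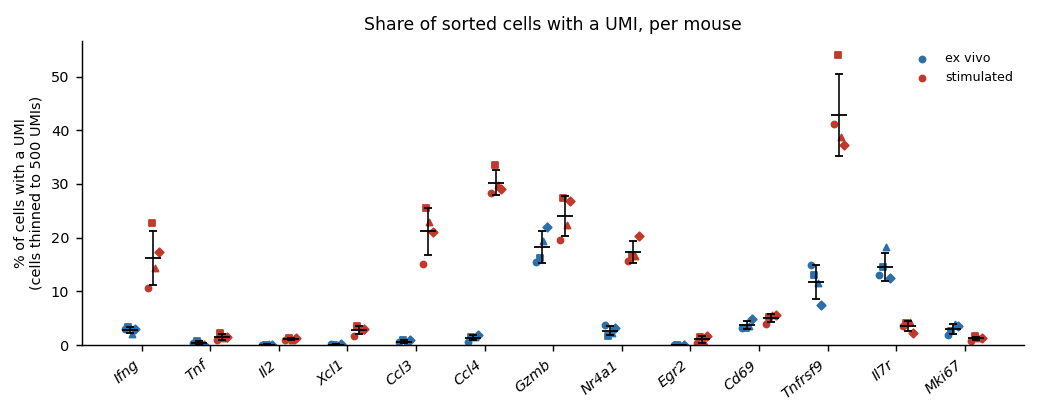
Percent of cells with at least 1 UMI, each cell thinned to 500 UMIs, for 13 genes in stimulated (red) and ex vivo (blue) libraries, with a point per library and a bar at the mean with its SD. Ccl4 is seen in 30.2% against 1.39% of cells and Il7r in 3.57% against 14.6%.

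Most pairs of effector transcripts were seen in the same stimulated cells more often than expected with no link. The expected counts treat all kept cells of a mouse as 1 population, with naive and B-like cells included. A mix of cells that respond with cells that do not could give such an excess alone. Co-detection was not tested within clusters or with the rRNA-like features left out. Of 21 pairs among Ifng, Tnf, Il2, Xcl1, Ccl3, Ccl4 and Gzmb, 17 had more co-detected cells than expected in all 4 mice, where chance gives 1.14 pairs, a count chosen after the data were seen. The planned log2 odds ratio was positive in all 4 mice for 19 pairs, where chance gives 2.14, since the 0.5 added to each count lifts rare pairs. Thus Tnf with Xcl1 had a positive value in mouse 1 with 0 co-detected cells against 0.268 expected. Over the 4 mice there were 1122 cells against 474 expected for Ccl3 with Ccl4, 54 against 14.4 for Ifng with Il2, 22 against 2.43 for Il2 with Xcl1 and 12 against 1.34 for Tnf with Il2. The mean log2 odds ratio was 3.75 ± 1.37 for Il2 with Xcl1, 3.70 ± 0.53 for Tnf with Il2, 3.58 ± 0.43 for Ccl3 with Ccl4 and 3.36 ± 1.20 for Ifng with Il2. The 2 pairs outside these 19 were Il2 with Gzmb (-0.36 ± 1.08) and Tnf with Gzmb (0.30 ± 1.13), each with an exact sign-flip p of 0.75, where 4 mice cannot go below 0.125. At 1000 UMIs per cell, the mean log2 odds ratio of Il2 with Gzmb was -1.27. At that depth 1 of the 21 pairs had fewer co-detected cells than expected (hypergeometric adjusted p under 5%), against 0 at 500 UMIs. Of the 6 cytokines and chemokines at 500 UMIs, 58.0 ± 5.14% of stimulated cells showed none, 21.7 ± 2.88% showed 1, 20.3 ± 4.18% showed 2 or more and 2.21 ± 0.978% showed 4 or more. In ex vivo cells, 94.7 ± 0.907% showed none and 0.285 ± 0.126% showed 2 or more.

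Clustering of the 8 sorted libraries gave 14 clusters. CD8 T-like clusters held 85.5 ± 9.25% of stimulated and 92.7 ± 3.87% of ex vivo cells, a naive T-like cluster held 7.04 ± 4.70% and 6.56 ± 3.58%, and a B-like cluster led by Cd74 and class II genes held 0.569 ± 0.367% and 0.526 ± 0.436%. Among the CD8 T-like clusters, cluster 4 was led by Ccl1, Il2, Xcl1 and Ifng, cluster 5 by interferon-induced genes, cluster 8 by heat shock genes, cluster 10 by cell cycle genes and cluster 1 by Gzmk, Klrg1, Gzma, S1pr5 and Trbv29. Cluster 1 made up 66.5% of ex vivo mouse 4. Clusters 9 and 13 had low UMI counts, stayed unnamed and held 6.93 ± 10.2% of stimulated cells, with 21.8% of stimulated mouse 1 in cluster 9. Cluster sizes were not tested between groups, since the genes that form the clusters differ between them. At resolution 1.0 there were 20 clusters.

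The comparison of ex vivo tetramer-sorted with bead-enriched CD8 cells set antigen-specific cells against a general T cell pool, both unstimulated. Effector molecules were far higher in the sorted cells. Gzma, the granzyme A protease, was at 2018 ± 1132 CPM in ex vivo and 3.28 ± 3.25 CPM in bead-enriched cells, Gzmb at 605 ± 70.1 against 1.42 ± 0.322 CPM, and Ccr2, a receptor for inflammatory chemokines, at 1596 ± 127 against 4.98 ± 1.32 CPM. Pdcd1, known as PD-1, was at 506 ± 44.9 against 3.46 ± 1.07 CPM. Genes of naive cells were lower, such as Id3, an inhibitor of E proteins, at 5.17 ± 1.67 against 109.9 ± 7.18 CPM and Il6ra, the IL-6 receptor, at 8.55 ± 1.61 against 227 ± 24.3 CPM.

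Of 10778 genes tested with edgeR, 7818 differed at 5%, 3735 higher and 4083 lower in the sorted cells, and for 6912 of them the groups did not overlap, which chance gives for 2 of 70 assignments of the 8 libraries. Sort, preparation, library run and animals all differ between the groups and cannot be separated. Xist, expressed from the inactive X chromosome of females, was at 331 ± 67.6 against 0.344 ± 0.176 CPM. The Y-linked Ddx3y and Eif2s3y had 0 UMIs in the ex vivo cells and 4072 and 1972 UMIs in the bead-enriched ones, at least 1405-fold and at least 680-fold lower in the sorted cells. The rRNA-like share of all kept cells, 34.6 ± 7.81% against 11.3 ± 6.88%, went with the groups as well.

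Effector differentiation genes and NK-type receptors were higher in 26 of 28 cases and lower in 1, with a median of 3.60 (camera adjusted p = 1.34e-29; adjusted p = 0.0143 with an estimated correlation). Klrg1, a receptor of terminal effector cells, was at 89.7 ± 76.1 against 0.322 ± 0.219 CPM (log2 fold change 7.88; 7.19 without mouse 4). Cytotoxic genes were higher in 12 of 14 cases and lower in 2, with a median of 2.99 (camera adjusted p = 2.75e-08; adjusted p = 0.0472 with an estimated correlation). By edgeR, Gzmb was at a log2 fold change of 8.73 (adjusted p = 8.77e-15), Ccr2 at 8.34 (adjusted p = 1.48e-14) and Gzma at 9.18 (adjusted p = 3.54e-10; 10.14 without the 10% OT-I library). Inhibitory receptors were higher in 7 of 10 cases and lower in 1, with a median of 3.52 (camera adjusted p = 2.17e-07; adjusted p = 0.025 with an estimated correlation). Pdcd1 was at 7.16, and Havcr2 at 6.69, with 42.3 ± 16.6 against 0.388 ± 0.239 CPM. Btla, an inhibitory receptor of resting lymphocytes, was lower at -1.71.

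Effector cytokines and chemokines were higher in 6 of 8 cases and lower in 1 (2 adjusted over the list alone), with a median of 4.47 (camera adjusted p = 0.00127; adjusted p = 0.191 with an estimated correlation, so this call was lost). Ifng was at 82.9 ± 30.6 against 1.06 ± 0.375 CPM, Tnf at 12.6 ± 7.81 against 1.58 ± 0.893 CPM, Ccl3 at 19.7 ± 9.03 against 0.445 ± 0.347 CPM, and Ccl4 at 36.8 ± 11.03 against 0.247 ± 0.353 CPM (log2 fold change 6.94; 8.28 without the 1% OT-I library). Xcl1 did not pass, at 2.20 ± 0.694 against 3.87 ± 1.24 CPM (log2 fold change -0.77, edgeR adjusted p = 0.0504), and passed without ex vivo mouse 1 (-1.03, adjusted p = 0.0274) or without the 0.01% OT-I library (-0.98, adjusted p = 0.0109). Il2 had too few counts to be tested. Of 23 receptor-induced transcription regulators, 20 were higher and 2 lower (21 and 2 adjusted over the list alone), with a median of 1.42 (camera adjusted p = 1.78e-12; adjusted p = 0.025 with an estimated correlation). Tnfaip3, an inhibitor of NF-kB, was at 1742 ± 364 against 52.8 ± 3.04 CPM and Fosl2, an AP-1 factor, at 299 ± 29.2 against 8.87 ± 0.575 CPM. Activation and costimulatory molecules were higher in 13 of 17 cases and lower in 2, with a median of 2.19 (camera adjusted p = 2.91e-08; adjusted p = 0.0478 with an estimated correlation). Tnfrsf9 was at 395 ± 137 against 13.8 ± 4.73 CPM and Cd40lg, the ligand of CD40, at 10.7 ± 3.87 against 0.256 ± 0.215 CPM.

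Feedback genes were higher in 18 of 24 cases and lower in 3 (18 and 4 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 7.29e-06; adjusted p = 0.0529 with an estimated correlation, so this call was lost). Dusp5, a phosphatase of ERK, was at 709 ± 141 against 32.1 ± 2.45 CPM and Cish, a SOCS family inhibitor, at 86.9 ± 7.89 against 2.86 ± 0.955 CPM. Glycolysis and hypoxia genes were higher in 20 of 22 cases and lower in none, with a median of 2.04 (camera adjusted p = 2.33e-19; adjusted p = 0.0478 with an estimated correlation). Hk2, a hexokinase, was at 181 ± 46.1 against 1.98 ± 0.107 CPM and Slc16a3, a lactate exporter, at 401 ± 58.6 against 4.83 ± 1.08 CPM. Cell cycle genes were higher in 24 of 34 cases and lower in 4 (24 and 5 adjusted over the list alone), with a median of 1.41 (camera adjusted p = 0.00116; adjusted p = 0.296 with an estimated correlation, so this call was lost). Ccna2, a cyclin of S phase, and Kif11, a spindle motor, had log2 fold changes of 3.26 and 3.16. Type I interferon genes were higher in 24 of 29 cases and lower in 2, with a median of 1.58 (camera adjusted p = 0.00812; adjusted p = 0.587 with an estimated correlation, so this call was lost). Ifit1, an RNA-binding antiviral protein, was at 95.1 ± 61.5 against 2.77 ± 0.919 CPM and Isg15, a ubiquitin-like modifier, at 67.8 ± 39.1 against 6.05 ± 0.583 CPM. This rise was mostly one of mice 1 to 3: their mean log2 CPM over the list was 5.64 to 6.11, while ex vivo mouse 4, at 4.33, lay within the bead-enriched range of 4.23 to 4.36. In mouse 4, Ifit1 was at 7.65 and Isg15 at 12.9 CPM.

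Naive and memory quiescence genes were lower in 18 of 20 cases and higher in 2, with a median of -1.30 (camera adjusted p = 1.05e-11; adjusted p = 0.025 with an estimated correlation). Ribosome biogenesis genes and MYC targets were lower in 23 of 30 cases and higher in 3, with a median of -0.76 (camera adjusted p = 0.000552; adjusted p = 0.258 with an estimated correlation, so this call was lost). Srm was at 2.13 ± 0.475 against 11.7 ± 1.20 CPM, while Odc1, the ornithine decarboxylase, was higher at 453 ± 162 against 47.5 ± 7.36 CPM. Cholesterol and lipid genes were lower in 12 of 19 cases and higher in 3, with a median of -0.67 (camera adjusted p = 0.0103; adjusted p = 0.191 with an estimated correlation, so this call was lost). Sc4mol, a sterol oxidase, was at 13.01 ± 2.35 against 45.6 ± 3.68 CPM. Oxidative phosphorylation genes were higher in 4 and lower in 14 of 30 cases (median -0.22, camera adjusted p = 0.321), with Atp5l, an ATP synthase subunit, and Ndufc1, a complex I subunit, at -1.40 and -1.35. The T cell receptor list holds Cd8a and Cd8b1, by which these cells were selected, so it was tested without them, a choice made after the data were seen. The other genes of the list were higher in 11 of 15 cases and lower in 3 (11 and 4 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.0299; adjusted p = 0.346 with an estimated correlation, so this call was lost). Trac, the receptor alpha constant region, was at 216 ± 42.8 against 88.5 ± 9.64 CPM and Zap70 at 463 ± 65.2 against 199.6 ± 6.94 CPM.

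Lists of other cells and of sample quality differed as well. Class II genes were lower in 8 of 8 cases, with a median of -4.36 (camera adjusted p = 0.00112; adjusted p = 0.265 with an estimated correlation). Without ex vivo mouse 1 that median was -6.02, and the log2 fold change of Cd74, at 8.03 ± 8.45 against 334 ± 29.97 CPM, went from -5.27 to -6.65. The 2 tested B cell genes were lower, with a median of -4.99 (camera adjusted p = 0.00181; adjusted p = 0.0648 with an estimated correlation), which ranged from -5.94 without ex vivo mouse 3 to -2.84 without ex vivo mouse 4. Ighm was at 27.0 ± 3.89 against 207 ± 17.6 CPM. Monocyte, macrophage and neutrophil genes were lower in 6 of 6 cases, with a median of -3.25 (camera adjusted p = 0.000543; adjusted p = 0.0975 with an estimated correlation). Restricted to T-like clusters, a choice made after seeing the data, that median was -1.06 (adjusted p = 0.0846) and the class II median -2.98 (adjusted p = 0.00918). Cst3 was at 76.0 ± 12.9 against 319.8 ± 72.6 CPM, and with that restriction its log2 fold change went from -2.07 to -0.26. The same restriction took Tnfrsf9 from 4.83 to 7.30, Dusp5 from 4.47 to 6.63, Havcr2 from 6.69 to 8.73 and the cytokine list from 4.47 to 5.63. CD4 and regulatory T cell genes were higher in 3 of 7 cases and lower in 1, with a median of 0.18 (camera adjusted p = 0.00821; adjusted p = 0.1003 with an estimated correlation), led by Ctla4 at 399.6 ± 116 against 4.11 ± 1.06 CPM.

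The dendritic cell list (2 of 6 higher, 3 lower, median -2.20, camera adjusted p = 0.0890), the plasma cell list (1 of 3 higher, 2 lower, median -3.47, adjusted p = 0.571), the NK cell list (2 of 4 higher, 2 lower, median -1.80, adjusted p = 0.412) and the gamma delta T cell list (2 of 2 higher, median 2.29, adjusted p = 0.384) were not called by camera. With fry these lists passed (adjusted p = 0.000116, 0.0479, 0.00462 and 0.00405 in the same order). Siglech, a receptor of plasmacytoid cells with 0 UMIs in the ex vivo cells, left the dendritic median at -2.20 when set at its bound. Their most abundant members were Bst2 at 0.61, Xbp1 at 0.61, Cd163l1 at 1.49 and Eomes at 0.83 (edgeR adjusted p = 0.0427). The Eomes call was lost with DESeq2 (0.90, adjusted p = 0.135), without ex vivo mouse 4 (0.32, adjusted p = 0.203), without ex vivo mouse 3 (0.88, adjusted p = 0.068) and without any one of the 4 bead-enriched libraries (adjusted p = 0.0650 to 0.0824). Car2 of erythroid cells and Itga2b of platelets were lower, at -1.44 and -1.57. Heat shock genes were higher in 8 of 13 cases and lower in none, with a median of 1.62 (camera adjusted p = 0.00152; adjusted p = 0.191 with an estimated correlation), with Hspa5 at a log2 fold change of 2.02. The mean log2 CPM over this list was 5.75 in the 1% OT-I library against 4.48 to 4.66 in the other bead-enriched libraries. It was 6.41 to 6.86 in the ex vivo libraries. Cytosolic ribosomal proteins were lower in 44 of 48 cases and higher in 1, with a median of -1.18 (camera adjusted p = 4.43e-07; adjusted p = 0.357 with an estimated correlation), and Rps14 was at -1.02. Mitochondrially encoded genes were higher in 3 and lower in 5 of 9 cases (median -0.78, camera adjusted p = 0.821), with mt-Rnr2 higher at 1.98. The genes with the lowest folds were carried by few cells: 263 of the 5736 bead-enriched CD8-detected cells (4.59%) lay outside T-like clusters, and they held 96.1% of Cd63, 94.5% of Fscn1 and 92.5% of Marcks UMIs. Cd63, a tetraspanin of lysosomes, had 0 against 2115 UMIs, at least 730-fold lower. Fscn1, an actin bundler of dendritic cells, had 1 against 4404 UMIs, a ratio of 4558 with a counting interval of 818 to 180087, and the log2 fold change was -11.01 (-12.79 without ex vivo mouse 3, which held that UMI). Marcks, a membrane substrate of protein kinase C, was at 0.463 ± 0.312 against 96.7 ± 18.2 CPM. With only T-like clusters the log2 fold changes were -7.13 for Cd63, -6.89 for Fscn1 and -4.75 for Marcks.

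On GRCm38, Gzma lies on chromosome 13 at 113093825 to 113100981, Gzmb on chromosome 14 at 56258838 to 56262260 and Pdcd1 on chromosome 1 at 94038305 to 94052553, all protein-coding. Xist, a long non-coding RNA, lies on chromosome X at 103460366 to 103483254, and the Trbv12-1 receptor segment on chromosome 6 at 41113550 to 41114067.

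The OT-I series asked how cells of 1 known receptor are seen when mixed in at falling percentages. The OT-I receptor uses the beta segment Trbv12-1 and an alpha segment of the Trav14 family, both of which other T cells also use. Of CD8-detected cells, Trbv12-1 was seen in 156 of 1459 (10.7%, 95% interval 9.15 to 12.4) at 10% OT-I, in 121 of 1568 (7.72%, 6.44 to 9.15) at 1%, in 65 of 1526 (4.26%, 3.30 to 5.40) at 0.1% and in 64 of 1183 (5.41%, 4.19 to 6.86) at 0.01%. Its level in CPM was lower at lower percentages, going from 56.9 (51.3 to 62.9) to 40.1 (35.3 to 45.3), 19.8 (16 to 24.3) and 18.8 (15.4 to 22.7), and the intervals of the last pair overlapped. Trav14 genes were seen in 22 (1.51%), 32 (2.04%), 9 (0.590%) and 14 cells (1.18%), with no order. Both segments were seen in 6, 2, 0 and 3 cells, and 0 of 1526 cells allows a share of up to 0.241%. With each cell thinned to 500 UMIs, Trbv12-1 was seen in 2.47%, 1.72%, 1.05% and 1.01% of cells. Over all kept cells, UMIs of all Trbv segments numbered 2507, 2265, 1122 and 1202 from 10% to 0.01%. Of these, Trbv12-1 made up 22.4%, 12.7%, 8.82% and 9.48%, so by this measure the order broke at the lowest percentages. Part of the fall in its level may thus lie in how well Trbv segments were detected, which was not tested.

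**Figure D4:**
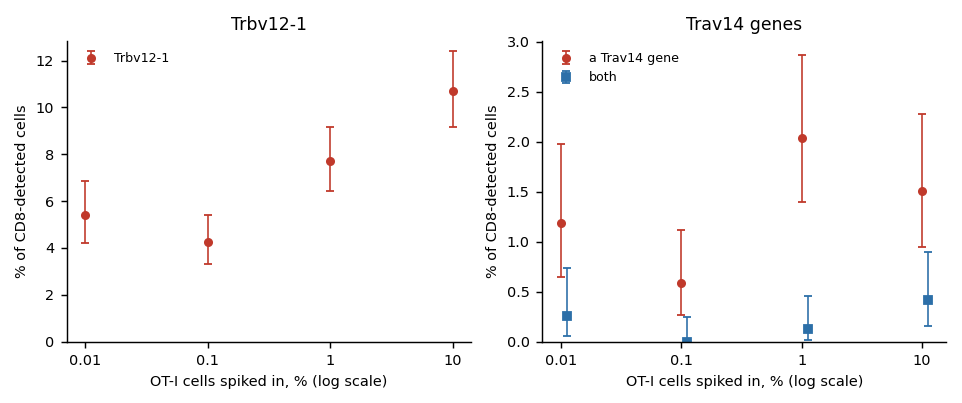
Percent of CD8-detected cells with a UMI of Trbv12-1 (left), or of a Trav14 gene or both segments (right), by OT-I percentage on a log axis, with a point per library and exact Clopper-Pearson intervals. Trbv12-1 lies at 10.7% of cells in the 10% library and at 5.41% in the 0.01% library.

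With 1 library per percentage these differences have no replicate check. CD8-detected cells made up 74.9%, 79.1%, 78.1% and 62.6% of kept cells, and 5, 6, 9 and 26 cells had Cd4 without CD8. In CD8-detected cells, 734 of 9657 genes with at least 100 UMIs were monotone in the percentage (7.60%, where chance gives 8.33%), with 15 rising and 9 falling at least 2-fold. Gzma (13.8-fold), Bbs10 (3.68-fold), Trbv12-1 (3.03-fold), Trbj2-2 (2.85-fold) and Rpl21-ps4 (2.70-fold) had the highest ratios of the 10% to the 0.01% library. Klf4, a factor of quiescence (0.216), Rab3d (0.387), Zscan18 (0.418), Mettl8 (0.450) and 4931406C07Rik (0.450) had the lowest. Over all kept cells, 1024 of 10373 genes were monotone (9.87%), with 70 rising and 54 falling at least 2-fold. The highest ratios were of Ighj1 (45.2-fold), Chac1 (23.1-fold), Gzma (19.3-fold), Tifab (6.16-fold) and Cenpf (4.92-fold). The genes falling most were Igkv4-80, with 0, 1, 1 and 735 UMIs from 10% to 0.01%, Gm22179, with 0, 2, 2 and 107, Gbp2b, Lif and Ptprm. Plasma-like cells held 98.1% of the 735 UMIs of Igkv4-80, and clusters 3 and 9, found in the 0.01% library alone, held 90.4% to 99.1% of the UMIs of the other 4 genes there. Without these clusters, a choice made after seeing the data, 853 of 10267 genes were monotone (8.31%), with 26 rising and 13 falling at least 2-fold.

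Clustering of the bead-enriched libraries gave 14 clusters, and 16 at resolution 1.0. Naive CD8 T-like clusters held 67.6 ± 8.78% of cells, CD8 T-like clusters 16.5 ± 2.66%, myeloid-like clusters 5.12 ± 1.00%, a B-like cluster 1.16 ± 0.509%, a plasma-like cluster 0.295 ± 0.127% and a cycling-like cluster 0.245 ± 0.0806%. The myeloid-like clusters were led by Lyz2, Fscn1, Cst3 and Il12b. Unnamed clusters held 9.07 ± 12.9%, among them cluster 7 led by Foxp3 and Ikzf2, which are factors of regulatory T cells, cluster 10 led by Siglech, and clusters 3 and 9, which were in the 0.01% library alone.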

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

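Of the tests in this part, that of damaged or near-empty barcodes, the levels without the rRNA-like features, the SD used on the depth of mouse 4 and the condition on Cd8b1 added to the test of doublets were chosen only after the results they bear on were seen. In 17 of 269 groups of values looked at, a library lay far from the others of its group by Dixon's ratio, where chance gives about 1 in 20 groups, or 13.45. Of these, 8 were in stimulated, 4 in ex vivo and 5 in bead-enriched libraries, and 1 of the 8 is of a gene that is counted but not reported here.

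The rRNA-like share was 21.6% in the 0.01% OT-I library against 7.15% to 9.33% in the others. Its naive CD8 T-like share was 54.4% against 71.3% to 72.7%, and its Xcl1 level 2.01 against 4.35 to 4.61 CPM. A group of 495 cells without Cd8a or Thy1 carried the rRNA-like and naive values: without them the rRNA-like share was 9.65% and the naive CD8 T-like share 73.7% of 1394 cells. The make-up of that naive share still differed. Cluster 1, a part of it with a median of 0.440 of the library's UMIs per cell, held 71 cells (3.76% of kept cells) here. In the other bead-enriched libraries it held 27.0% to 35.4%. Stimulated mouse 3 had naive T-like cells at 14.1% against 4.23% to 4.97%, B-like cells at 1.118% against 0.355% to 0.406% and Xbp1 at 164 against 141 to 143 CPM. Stimulated mouse 4 had lower co-detection of Ifng with Il2 (log2 odds ratio 1.58 against 3.79 to 4.16) and with Ccl4 (1.41 against 2.65 to 2.79), and Sorl1 at 95.2 against 110.5 to 113 CPM. Ighm was at 13.9 CPM in stimulated mouse 1 against 23.3 to 24.4. In CD8-detected cells, ex vivo mouse 4 had Klrg1 at 203 against 43.1 to 60.1 CPM, Atp5l at 1.21 against 2.52 to 2.67 CPM and Marcks at 0 against 0.557 to 0.668 CPM. Fscn1 was at 0.139 CPM in ex vivo mouse 3, from 1 UMI, and at 0 in the other ex vivo libraries. Itga2b was at 7.66 CPM in the 0.1% library against 4.89 to 5.24, and Sc4mol at 51.0 CPM in the 1% library against 43.0 to 44.3.

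In the 0.01% library, 495 of 1889 cells (26.2%, 95% interval 24.2 to 28.2) formed clusters of their own, against 0 of 5882 cells in the other bead-enriched libraries, and none of the 495 had a UMI of Cd8a, Cd8b1 or Thy1. Other T cell or leukocyte genes were seen in part of them, with Cd3e in 62 cells, Trac in 43 and Ptprc in 310. Rpl10l had 821 UMIs in the 495 cells and 2 in the library's other cells, and Actbl2 432 and 2, while Rplp0 had 14 and 30959. These genes are examples chosen after their values were seen. The rRNA-like features took 64.5% of the UMIs of the 495 cells. Without these features the median of 1330 UMIs was 0.342 of that of the library's other cells. Near-empty barcodes would hold the library's own transcripts in their usual proportions, but of the 100 most abundant other genes 25 were under 0.1 of their level, which argues against them. Damaged cells could lose some transcripts more than others, so this count cannot exclude damage, which stays open. Another cell type of the mouse would keep its mitochondrial transcripts, but the protein genes of mitochondria were at a median of 0.0504 of the other cells' level (0.128 without the rRNA-like features), which argues against it. Cells of another species, whose reads align in part to mouse genes, would have B2m at 0.2 of the other cells' level or less. B2m was at 0.145 over all UMIs but at 0.369 without the rRNA-like features, so this stays a hypothesis. A carry-over from another array or library stays open, and no further biological explanation was tested.

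Class II transcripts in CD8-detected cells of the bead-enriched libraries sat mostly in few cells: 140 of 5736 cells held 84.0% of 26396 UMIs. Free RNA would spread over all cells, so 84.0% argues against it as the main source. Doublets of T cells with antigen-presenting cells could give that 84.0%, and the 140 cells had a median of 7538 UMIs against 3039.5 in cells with no class II UMI, but antigen-presenting cells that carry Cd8a themselves may give it too. The latter would lack Cd8b1, whose share was 0.606 of that in cells with no class II UMI. This lies between the bounds set for either explanation, so it cannot tell the pair apart. CD3 transcripts were seen in 48.6% of the 140 cells against 92.6% of cells with no class II UMI, despite the higher UMI counts. That argues against doublets with T cells as the source of all 140, and leaves them open for a part. No further biological explanation was tested.

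Ex vivo mouse 4 had a mean share of Gzmk, Klrg1, Gzma and S1pr5 of 15.5% of cells at 500 UMIs, against 5.50%, 8.29% and 8.33% in mice 1 to 3. These 4 genes and Trbv29 are top genes of cluster 1 of the sorted libraries, which made up 66.5% of this library. Neither their excess here nor their link to Trbv29 in mouse 4 is thus independent support. A state of all its sorted cells is argued against, since among cells with another Trbv segment than Trbv29 mouse 4 differed from the highest other mouse by -0.792 percentage points. Cells with Trbv29 were higher than cells with another segment in 3 of the 4 ex vivo libraries (25.1% against 8.33% in mouse 4, 16.4% against 7.44% in mouse 2, and 9.44% against 9.13% in mouse 3, which is near no difference and rests on 45 cells). In mouse 1 they were lower, at 1.92% against 6.05%. With mouse 4 set aside, only mouse 2 was clearly higher, so a link to Trbv29 may hold in some mice only. The excess at 500 UMIs was 7.22 percentage points, or 4.45 SDs of mice 1 to 3 (SD 1.62), where low depth alone would leave none. The rRNA-like features took fewer UMIs in mouse 4 (25.3% against 33.9% to 44.4%), which favours it, but with them left out before thinning the excess was still 6.80 points, or 3.13 SDs. An excess left at equal depth argues against low depth as the only cause, although it falls short of the 10 points set beforehand. Its size in SDs is no test, since these genes already marked this library in the clusters. No difference between these mice is named by the labels, so a biological difference between them was not tested.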

How the results depend on the processing

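Tests chosen only after the data were seen are those with the rRNA-like features left out, without the low-UMI, naive T-like and B-like clusters, with only T-like clusters or without the selecting genes against the bead-enriched libraries, the OT-I genes over CD8-detected cells alone or without clusters 3 and 9, and the counts of co-detected cells. The count of changed genes in stimulated cells ran from 4152 (means of scaled cells with limma) to 6723 (mouse as a block), and without a replicate from 4575 to 5765. Against bead-enriched cells it ran from 6761 (thinned libraries) to 8933 (no filter on low counts), and without a library from 7503 to 8162. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes in each comparison, the real one. In the first comparison, the real split gave 5636 genes and the highest other 0 by edgeR (1113 at an unadjusted p under 0.05), also among the 8 splits that part all 4 pairs. In the other comparison they gave 7818 and 0 (758). Any other split mixes the groups, so a real difference widens the spread within its sides. The counts of 0 thus do not measure false calls. For the first comparison the rank of the real split argues against chance. Bead-enriched libraries may be technical repeats, so in the other comparison the splits cannot weigh chance between animals. Depth limits the rarer transcripts most: ex vivo mouse 4 held 2973829 UMIs.

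Of 682 values of genes named in the first comparison, 668 kept direction and side of the threshold, and of 569 in the other, 568 did. So did 114 of 130 and 87 of 102 values of lists, 43 of 56 of shares and 18 of 21 of co-detection. With the estimated correlation, 5 instead of 13 lists were called in the first comparison and 7 instead of 20 in the other. With fry, 18 lists were called in the first comparison. With mouse as a block, 6723 genes and 13 lists passed, and the dendritic list's test turned upward (median 0.13). Ctla4, Eomes, Ighm and mt-Rnr2 then passed, and no other gene named by the rule changed its call. In the paired sign-flip test no share could pass, since its smallest p is 0.125. Itga2b was at 0.0793 without the low-UMI, naive T-like and B-like clusters, and the NK list at 1.00 with only T-like clusters. At 1000 UMIs the log2 odds ratio was -0.0724 for Tnf with Gzmb, -0.0380 for Xcl1 with Gzmb and 1.98 for Ifng with Ccl3. At 500 UMIs, Trbv12-1 was seen in 2.47%, 1.72%, 1.05% and 1.01% of cells. Over CD8-detected cells, 15 genes rose and 9 fell with OT-I, and 26 and 13 without clusters 3 and 9. Why these values changed was not tested. Without a replicate, values ran from -0.41 to 0.88 for Cd74, -0.35 to 0.23 for Itga2b, -0.24 to 0.21 for the mitochondrial list, -0.35 to 0.55 for the B cell list and -0.82 to 0.48 for the class II list. Against bead-enriched cells, the mitochondrial list ran from -0.87 to -0.59. Tnf with Gzmb ran from -0.0309 to 0.84 and Il2 with Gzmb from -0.75 to 0.11.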

Other observations

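The gene sets and tests in this part were chosen only after the values were seen. Among the genes that rose in stimulated cells were enzymes of serine synthesis, the folate cycle and nucleotide synthesis. Of 29 tested, 23 rose, 1 fell and 5 did not pass by edgeR, with a median log2 fold change of 1.63, and 22 of the risers were higher in all 4 mice. Over all genes, 2892 of 10459 rose. As the sets were picked from the same table, no test of enrichment was made and the theme is a hypothesis. Shmt1, which moves a carbon unit from serine to folate in the cytosol, was at 35.3 ± 3.15 against 1.116 ± 0.248 CPM (log2 fold change 4.95), and Mthfd1, which interconverts folate forms, at 97.8 ± 11.5 against 4.63 ± 1.15 CPM (4.32). Gcsh of the glycine cleavage system was at 4.24, Ctps, the CTP synthase, at 3.81, Slc19a1, the folate carrier, at 3.41, and Pfas and Gart of purine synthesis at 3.27 and 2.90. Tyms, which makes thymidylate in dividing cells, was at -0.58 and did not pass (edgeR adjusted p = 0.0578).

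Amino acid carriers rose in 8 of 11 cases and fell in 1, with a median of 1.02. Slc7a1, the arginine and lysine carrier, was at 324 ± 11.997 against 38.04 ± 5.17 CPM. Slc7a5, a carrier of large neutral amino acids, was at 2.84 and Slc1a5, a glutamine carrier, at 2.03, while Slc3a2, the partner chain of Slc7a5, was at 1.01. Slc38a9, a lysosomal arginine sensor, fell by 0.66.

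Libraries of the same mouse may share expanded receptor segments. The usage of Trbv segments overlapped by 82.1% to 89.1% between the stimulated and ex vivo libraries of 1 mouse and by 38.05% to 63.5% between different mice. Of the 24 ways to pair the libraries, only 1 reached the summed overlap of the same-mouse pairing, the pairing itself (exact p = 0.0417). This is consistent with libraries of one mouse sharing receptor segments. Trbv29 took 48.8% of Trbv UMIs in stimulated and 53.1% in ex vivo mouse 4, and Trbv2 took 38.3% and 35.9% in mouse 2. The effective number of segments was 3.24 to 8.68 in the sorted and 10.4 to 15.1 in the bead-enriched libraries.

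Antibody segments in the bead-enriched libraries came from few cells. Ighv1-39 had 847 UMIs in 21 cells of the 1% library, Igkv4-80 had 735 UMIs in 15 cells of the 0.01% library and Ighv14-3 had 448 UMIs in 6 cells of the 10% library. Sex-linked transcripts parted the preparations wholly: Xist had 677 to 3547 UMIs per sorted library and 3 to 5 per bead-enriched one, and Ddx3y had 0 to 2 and 977 to 1489.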
